A study of Homo sapiens with 6 samples.

How the data were processed

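Total RNA sequencing libraries were made from 2 human liver tumour cell lines, Huh6 and Huh7, each carrying a stably transfected expression construct kept under hygromycin at 200 µg/ml. The 6 libraries fall into 6 groups of 1 library each, with tRFP (a red fluorescent protein, the control) and APOOP1 in Huh6, and tRFP, APOOP1, HAVCR1 and TIMD4 in Huh7. The grouping was taken from the sample labels, and no column belonged to any other sample.

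The authors deposited 2 sheets with the same 58884 gene rows. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.38, counted per gene with featureCounts 2.0.0 and normalized with edgeR on genome build GRCh38. The aligner, its settings, the annotation release and the strand setting are not given in the sources used here. One deposited sheet holds raw counts per gene, with no normalization. The other deposited sheet holds CPM, counts divided by a scaled library size, which the authors made with edgeR. Each of its values was the count divided by a single constant per library. The exact scaling behind those constants is not stated, so the counts were used for every main result and the CPM sheet served as an alternative. Without the strand setting, reads from a gene and from a gene on the opposite strand could not be told apart.

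Of the rows, 33479 had a count in any library, 56939 carried a symbol and 58611 matched an identifier in GENCODE 29, which supplied coordinates on GRCh38. Library totals ran from 15467658 to 17390764 counts. A gene with 0 counts was given a floor of 3 counts, which corresponded to 0.172 to 0.194 CPM, and folds over it are given per library, or over the group in the comparison of the lines. They leave out the counting error of the higher value. Counts were scaled with TMM factors in edgeR 4.0.16 under R 4.3.3. Reads carried no molecular identifiers, so every interval and floor covers counting error only.

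With 1 library per group, 5 comparisons within a line had no replicate check and no p-value in the main analysis. For these, log2 CPM was computed with a prior count of 2, genes with at least 50 counts in either library were taken as measured, and genes at 2-fold or more were counted. Folds are ratios of scaled CPM, with exact conditional binomial 95% intervals. Each of these intervals compares 2 libraries, not 2 conditions. A gene was set apart in a Huh7 library when it lay 2-fold or more above, or below, all 3 other Huh7 libraries.

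Before the data were examined, 31 gene lists were fixed from textbook knowledge. The median log2 difference of each list, over members with at least 10 counts in either library, was placed among the medians of 10000 random lists of the same size, drawn from genes within 100 ranks in mean expression. A list was called outside when its median lay beyond the central 95% of those random medians. At the ends of the expression ranking the draw was corrected after first results had been seen, so that it stayed within the ranking. Another 2 lists, YAP/TEAD targets and SRF and actin genes, were added after the data were seen and are named as such.

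The APOOP1 effect across lines was tested with edgeR's quasi-likelihood test (TMM, filterByExpr, cell line as block, Benjamini-Hochberg 5%) on the 4 libraries of tRFP and APOOP1. The 2 lines served as replicates, which left 1 residual degree of freedom, and the common biological coefficient of variation was 0.107. The Huh6 and Huh7 lines were compared with the same test over all 6 libraries, with 4 residual degrees of freedom and a coefficient of variation of 0.101, so that the construct effects formed part of the spread. Standard errors of fitted log2 fold changes are those implied by the quasi-likelihood F statistic. Correlations across genes were computed between differences that shared no library. Genes are not independent replicates, so these have no p-value.

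The 2-fold count, the fits and the gene lists were tested on simulated data first. For the 2-fold count, simulated Poisson counts with unchanged genes gave 1 gene per comparison, negative binomial counts gave 5 to 9 genes, and all 100 genes changed 4-fold were recovered in each comparison. No group had replicates, so the spread of the negative binomial counts was not measured within any group. In the simulated fit of APOOP1 across lines, 17 of 50 genes changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 4-fold were recovered, with 10 false calls among 16307 genes. There each changed gene had the same fold in both lines, a mean of at least 50 counts and the common dispersion. The real APOOP1 differences varied between the lines, so these recoveries need not hold for the data. In the simulated fit of the lines, 32 of 50 genes changed 1.5-fold and 50 of 50 changed 2-fold were recovered, with 7 false calls among 16006 genes. For the lists, run on the 15262 genes of the HAVCR1 comparison, 20 of 20 shifted lists and 6 of 100 unshifted lists lay outside. That does not show how often lists whose members vary together lie outside without a construct effect, because random lists draw genes independently.

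Genes were named by a rule fixed before the data were examined. It took the overexpressed genes, APOO and the measured genes of the 5q33.3 locus. For HAVCR1 and TIMD4 it took up to 10 genes each way among those set apart. For APOOP1 it took genes at 2-fold the same way in both lines and the 10 smallest p-values of the fit. For the lines it took the 10 largest differences each way. For each list it took up to 3 members each way at 2-fold or more. Genes named outside this rule are given as chosen after their values were seen.

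The alternatives were DESeq2 1.42.0 size factors, library totals, the deposited CPM, minimum counts of 10 and 200, a threshold of 1.5-fold, a prior count of 0.5, the mean of the 3 other Huh7 libraries in place of the control, an additive edgeR fit of line and construct over all 6 libraries, the DESeq2 Wald test, looser and stricter filters, random lists not matched on expression, list members with at least 50 counts, fits without the block, and fits without each library in turn. The additive fit takes its spread from the APOOP1 difference between lines, so the lone HAVCR1 or TIMD4 library is assumed to vary alike. The mean of the 3 others for APOOP1, lists restricted to protein-coding genes and lists without the overexpressed genes were added after the data were seen. Transcript sequences were compared with blastn 2.17.0. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Sequences of the constructs and the reads themselves were not used here.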

Results

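The series asked which gene at the chromosome 5q33.3 locus acts on triglycerides and lipid metabolism in liver cells. HAVCR1 and TIMD4, receptors for phosphatidylserine, and APOOP1, a processed pseudogene of APOO, were each overexpressed in Huh7, a hepatocellular carcinoma line, and APOOP1 also in Huh6, a hepatoblastoma line. Gene counts from total RNA were obtained for 1 library per line and construct, 2 in Huh6 and 4 in Huh7, with tRFP as the control in both lines. The libraries held 15784236 counts for Huh6 tRFP, 15467658 for Huh6 APOOP1, 17390764 for Huh7 tRFP, 16579203 for Huh7 APOOP1, 15819277 for Huh7 HAVCR1 and 16304809 for Huh7 TIMD4. Comparisons within a line therefore had no replicate check, and their intervals cover counting error only. In those comparisons, higher and lower describe single libraries.

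By fold over its background, TIMD4 (ENSG00000145850) was strongly overexpressed, whereas HAVCR1 (ENSG00000113249) rose by a small fold and APOOP1 (ENSG00000270560) stayed at few counts. TIMD4 reached 125 CPM in its own library against 2.40 in the Huh7 control, a fold of 52.0 (95% interval 38.4 to 72.4). HAVCR1 was already expressed at 195 CPM in the Huh7 control and reached 318 CPM in its own library, a fold of 1.63 (1.56 to 1.70), and it was 1.47-fold (1.41 to 1.54) above the next highest Huh7 library. In CPM, the rise of HAVCR1 over the control was about as large as that of TIMD4. APOOP1 had 10 counts in the Huh7 APOOP1 library against 0 in the control, a fold with a lower 95% bound of 2.36. In Huh6 it had 10 counts against 4, a fold of 2.60 (0.75 to 11.4), a difference not detectable at this depth. APOO, the parent gene, encodes a subunit of the mitochondrial MICOS complex and differed little, by 0.939-fold (0.834 to 1.06) in Huh7 and 1.0-fold (0.807 to 1.24) in Huh6.

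**Figure D1:**
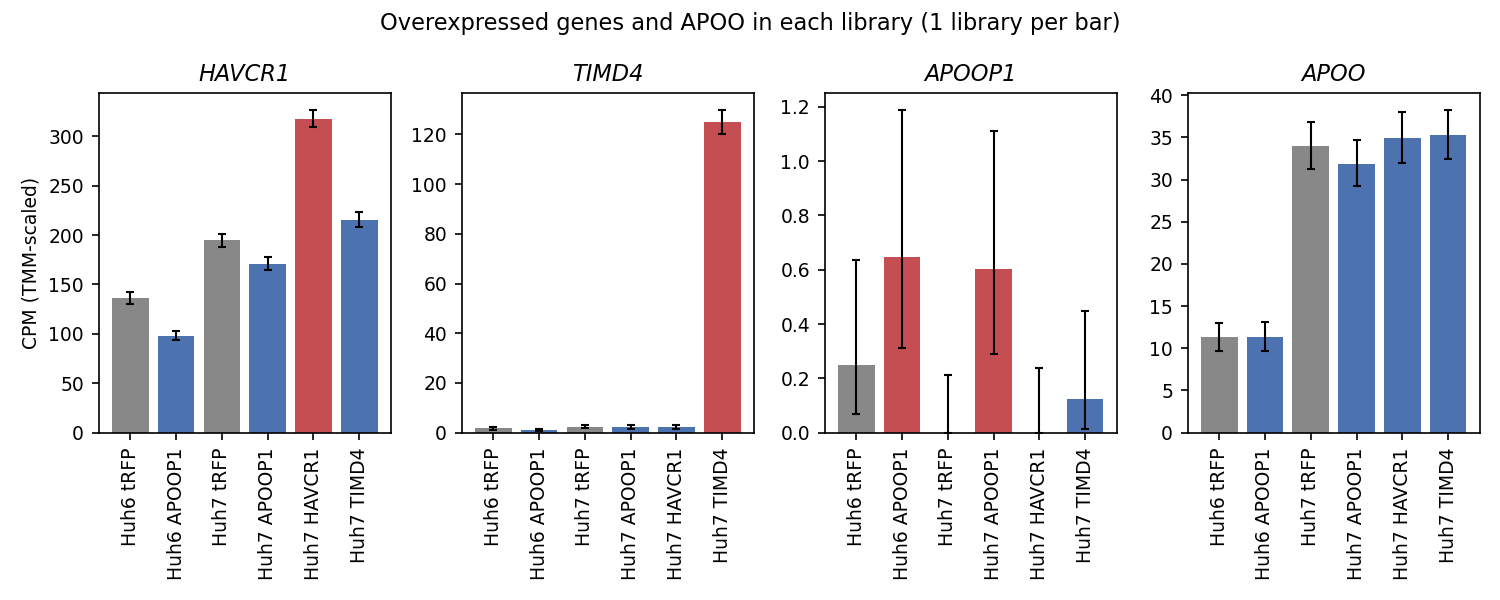
CPM (counts scaled to library size with TMM, vertical axes) of HAVCR1, TIMD4, APOOP1 and APOO in each of the 6 libraries. Each bar is 1 library with its 95% Poisson interval, grey for the tRFP controls, red for the library that carries the gene's own construct and blue for the others. TIMD4 reached 125 CPM in its own library, HAVCR1 reached 318 CPM over a control of 195, and APOOP1 stayed below 1 CPM.

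On GRCh38, TIMD4 lies on chromosome 5 at 156919282 to 156963255 and HAVCR1 at 157029413 to 157059119, both on the reverse strand. APOOP1 lies at 156924119 to 156924710 on the forward strand, inside a TIMD4 intron, and overlaps 0 TIMD4 exons. It had 2 counts in the TIMD4 library. Since the strand setting of the counting is unknown and APOOP1 resembles APOO, its counts are uncertain. Of the neighbouring genes, CYFIP2, a regulator of actin assembly, was 2.08-fold (1.40 to 3.14) higher in the Huh7 APOOP1 library and at 1.05-fold (0.960 to 1.14) in Huh6. UBLCP1, a proteasome phosphatase, was 1.32-fold (1.15 to 1.51) higher with APOOP1 in Huh7 and at 0.946-fold (0.869 to 1.03) in Huh6. TTC1 was 1.16-fold higher with APOOP1 in both lines (1.07 to 1.26 in Huh7, 1.1 to 1.23 in Huh6). In Huh7, TTC1 was also at 1.13-fold (1.03 to 1.23) in the HAVCR1 library and 1.08-fold (0.989 to 1.18) in the TIMD4 library. UBLCP1 was at 1.15-fold (1.0 to 1.33) in the HAVCR1 library and 1.16-fold (lower bound 1.01) in the TIMD4 library. The small Huh7 rises of TTC1 and UBLCP1 were therefore not seen with APOOP1 alone. HAVCR1 was lower with APOOP1 in both lines, at 0.88-fold (0.837 to 0.925) in Huh7 and 0.723-fold (0.677 to 0.773) in Huh6. The Huh6 APOOP1 library also had THG1L at 1.23-fold (1.04 to 1.46), LSM11 at 0.812-fold (0.698 to 0.945) and CLINT1 at 0.9-fold (0.858 to 0.944). The ubiquitin ligase gene RNF145 was at 0.843-fold (0.747 to 0.951) in the HAVCR1 library. The clathrin adaptor CLINT1 was at 1.07-fold (1.02 to 1.14) in the HAVCR1 library and 1.05-fold (0.998 to 1.11) in the TIMD4 library.

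The HAVCR1 library was compared with the tRFP control to find what its overexpression changes in Huh7. TAGLN, an actin-binding protein, was 3.05-fold (2.5 to 3.73) higher, the matricellular protein CYR61 2.38-fold (2.13 to 2.65), the chemokine CXCL8 2.31-fold (2.06 to 2.58) and the progenitor marker PROM1 2.49-fold (2.23 to 2.78). AXL, a receptor tyrosine kinase that binds phosphatidylserine through GAS6, was 2.14-fold (1.39 to 3.37) higher. PCK1, a key enzyme of gluconeogenesis, was at 0.402-fold (0.270 to 0.588) and MLXIPL, the carbohydrate-responsive activator of lipogenesis, at 0.416-fold (0.236 to 0.706), with 20 counts against 54. Of 11612 genes measured, 44 were higher and 16 lower by 2-fold or more. With a minimum of 10 counts, where counting error alone can reach 2-fold, 212 were higher and 289 lower.

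Among genes chosen after their values were seen, the keratin KRT80 was 4.74-fold (4.13 to 5.44) higher and the collagen COL12A1 5.24-fold (3.25 to 8.84) higher in the HAVCR1 library. The calcium pump ATP2B2 was at 0.367-fold (0.243 to 0.542), and SLC2A4, the insulin-responsive glucose transporter, at 0.381-fold (0.214 to 0.651). KRT80 was higher in the TIMD4 and APOOP1 libraries too, and 0 genes were set apart in the HAVCR1 library from all 3 other Huh7 libraries. Against the mean of those 3 libraries, 0 genes were higher and 5 lower. That mean includes the APOOP1 library, which differed most from the control, so these counts cannot decide what HAVCR1 overexpression changes.

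Several lipid gene groups were slightly lower in the HAVCR1 library, with medians far below a 2-fold difference. Cholesterol synthesis genes had a median log2 difference of -0.13, with 20 of 23 members below 0. Apolipoproteins and VLDL assembly stood at -0.15 (18 of 21 below 0), fatty acid oxidation at -0.099 (18 of 26), LXR targets at -0.13 (9 of 14), lipoprotein uptake at -0.079 (11 of 15) and fatty acid synthesis at -0.037 (16 of 24). Triglyceride synthesis at -0.049, triglyceride hydrolysis at 0.023, lipid droplet coat genes at -0.00056 and bile acid genes at -0.060 lay within the range of random lists. Outside the lipid lists, hepatocyte genes stood at -0.11 (26 of 29 below 0), acute phase genes at -0.26 and ATF4 stress genes at -0.15. Epithelial and mesenchymal genes stood at 0.29, cholangiocyte and progenitor markers at 0.24, immediate early genes at 0.20, NF-kB genes at 0.18 and cell cycle genes at 0.11. Nuclear-retained and non-polyadenylated RNA, a marker of how RNA was prepared, stood at -0.17, but at -0.0503 (percentile 20.71) with members of at least 50 counts and at 0.0611 with protein-coding genes only, both within the range.

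In this comparison 15 of 30 lists lay outside the central 95% of their random lists. Members of a list can vary together between libraries, which random lists leave out. Lying outside therefore does not by itself show a construct effect, here or in the comparisons below. Against the mean of the 3 other Huh7 libraries, 6 of those 15 lay outside the same way, among them LXR targets at -0.090 and lipoprotein uptake at -0.057. Cholesterol synthesis then stood at -0.0037 and apolipoproteins at -0.0044, both within their range, and fatty acid synthesis turned to 0.018 and acute phase genes to 0.032. Epithelial and mesenchymal genes fell to 0.0092, cholangiocyte and progenitor markers to 0.063, immediate early genes to 0.015, NF-kB genes to 0.038 and fatty acid oxidation to -0.0049, all within their range as well. The mean used there includes the APOOP1 library, in which the medians of the lists that lost the call lay on the same side of 0 against the control. Among them, apolipoproteins stood at -0.0936 there, within their random range. The losses therefore cannot decide whether HAVCR1 changed them. Against unmatched random lists, fatty acid synthesis (percentile 14.7) and lipoprotein uptake (8.19) no longer lay outside.

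To find what TIMD4 overexpression changes, its library was compared with the same tRFP control, from which it differed in the fewest genes of the 3 constructs. Beyond TIMD4, 1 gene was set apart from all 3 other Huh7 libraries, the folate receptor FOLR1, at 0.361-fold (0.171 to 0.709) of the control with 12 counts against 36. Of 11601 genes measured, 8 were higher and 6 lower by 2-fold or more, where simulated negative binomial counts of unchanged genes gave 8 in all. The spread of those simulated counts was not measured between replicates, so they are a rough guide only. Among genes chosen after their values were seen, KRT80 was 2.75-fold (2.38 to 3.19) higher, the tubulin TUBA1A 2.79-fold (1.97 to 3.99) and the actin-associated NEXN 2.09-fold (1.49 to 2.94). The receptor GPR153 was at 0.383-fold (0.227 to 0.624). Against the mean of the 3 other Huh7 libraries, which include APOOP1, 3 genes were higher and 11 lower. With a minimum of 10 counts, where counting error alone can reach 2-fold, 148 were higher and 236 lower than in the control.

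Several lipid groups stood slightly below 0 in the TIMD4 library as well. Cholesterol synthesis stood at -0.076 (18 of 23 below 0), apolipoproteins and VLDL assembly at -0.097 (17 of 21), fatty acid oxidation at -0.073 (17 of 26) and triglyceride hydrolysis at -0.079 (8 of 15). Triglyceride synthesis at -0.053 and fatty acid synthesis at -0.0054 lay within the random range. Hepatocyte genes stood at -0.080, xenobiotic metabolism at -0.11, epithelial and mesenchymal genes at 0.17, cholangiocyte markers at 0.16, immediate early genes at 0.14, cell cycle genes at 0.088 and mitochondrial genome transcripts at 0.081. In all, 13 of 30 lists lay outside, and 2 of these did so the same way against the mean of the 3 other Huh7 libraries. Against that mean 7 of the 13 turned direction, cholesterol synthesis to 0.083, hepatocyte genes to 0.037 and epithelial and mesenchymal genes to -0.14 among them. That mean includes the APOOP1 library, where those 7 lists were shifted further the same way from the control. The turns therefore cannot decide whether TIMD4 changed them. Against unmatched random lists 6 of the 13 no longer lay outside, cholesterol synthesis (percentile 3.35) among them.

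The Huh7 APOOP1 library, set against the same control to find what the pseudogene changes, differed most of the 3. Of 11751 genes measured, 268 were higher and 55 lower than in the tRFP control by 2-fold or more. With a minimum of 10 counts, where counting error alone can reach 2-fold, the numbers were 610 and 347, and at 1.5-fold 691 and 373. From all 3 other Huh7 libraries 80 genes were set apart, against 11 for tRFP, 0 for HAVCR1 and 2 for TIMD4. KRT80 was 13.1-fold (11.5 to 14.9) higher, TAGLN 9.88-fold (8.29 to 11.8), CYR61 5.19-fold (4.70 to 5.73), PROM1 5.06-fold (4.58 to 5.61), AXL 5.15-fold (3.52 to 7.73) and CXCL8 4.44-fold (4.01 to 4.92). The growth factor TGFB2 was 4.77-fold (4.29 to 5.31) higher and the intermediate filament VIM 2.24-fold (2.15 to 2.33). NPPB, which encodes a natriuretic peptide and was chosen after its values were seen, had 158 counts against 1.

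Liver and lipid genes were among those lower in the Huh7 APOOP1 library. FABP1, the liver fatty acid binding protein, was at 0.457-fold (0.442 to 0.472), GPAM, which starts triglyceride synthesis in mitochondria, at 0.442-fold (0.314 to 0.616), TM6SF2, which acts in VLDL lipidation, at 0.456-fold (0.285 to 0.716) and the bile acid receptor NR1H4 at 0.339-fold (0.287 to 0.398). BAAT, which conjugates bile acids, was 3.46-fold (2.97 to 4.05) higher. Below 2-fold, and chosen after their values were seen, MTTP, which loads lipid onto APOB, was at 0.551-fold (0.494 to 0.615), APOB at 0.635-fold (0.620 to 0.650) and ALB, the serum albumin gene, at 0.719-fold (0.710 to 0.728).

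Cholesterol synthesis had the lowest median of the lipid lists in the Huh7 APOOP1 library, at -0.36, with 22 of 23 members below 0. Fatty acid oxidation stood at -0.20 (21 of 26 below 0), triglyceride synthesis at -0.17 (12 of 15) and fatty acid synthesis at -0.16 (16 of 24). Apolipoproteins at -0.094, lipoprotein uptake at 0.033, triglyceride hydrolysis at 0.11 and lipid droplet coat genes at -0.025 lay within the random range. Hepatocyte genes stood at -0.29, acute phase genes at -0.35 and ATF4 stress genes at -0.24. Epithelial and mesenchymal genes stood at 0.64 (18 of 21 above 0), NF-kB genes at 0.54, cholangiocyte markers at 0.44, immediate early genes at 0.40 and stromal markers, with 5 members, at 0.73. In all, 12 of 30 lists lay outside, and 11 of these, all but the stromal markers, did so the same way against the mean of the 3 other Huh7 libraries. Against that mean 175 genes were higher and 15 lower, an alternative added after the data were seen. Against unmatched random lists triglyceride synthesis (percentile 3.57) no longer lay outside.

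In Huh6, the APOOP1 library differed from its control in fewer genes, with 26 higher and 41 lower of 11855 measured. The NF-kB subunit RELB was 2.11-fold (1.39 to 3.26) higher. The sterol exporter ABCG8 was at 0.422-fold (0.305 to 0.576) and the plasma protein ITIH2 at 0.425-fold (0.391 to 0.461). Chosen after their values were seen, the organic anion transporter SLC22A7 was at 0.258-fold (0.173 to 0.376) and MTTP at 0.676-fold (0.629 to 0.727). Hepatocyte genes had a median of -0.34, with 27 of 30 members below 0, bile acid genes -0.32, LXR targets -0.31, apolipoproteins -0.17, fatty acid synthesis -0.11 and fatty acid oxidation -0.090. NF-kB genes stood at 0.36, immediate early genes at 0.28, with 14 of 14 above 0, ATF4 stress genes at 0.20, p53 targets at 0.17 and lipid droplet coat genes at 0.13, at the edge of the random range. With members of at least 50 counts, lipid droplet coat genes stood at 0.0504 (percentile 75.64). They also lost the call against unmatched lists (96.25) and with protein-coding genes only (97.11), in each case within the random range. Cholesterol synthesis at -0.039 and triglyceride synthesis at 0.015 lay within it. In all, 16 of 31 lists lay outside, of which 5 no longer did so against unmatched random lists, fatty acid synthesis (percentile 3.04) and fatty acid oxidation (5.45) among them.

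**Figure D2:**
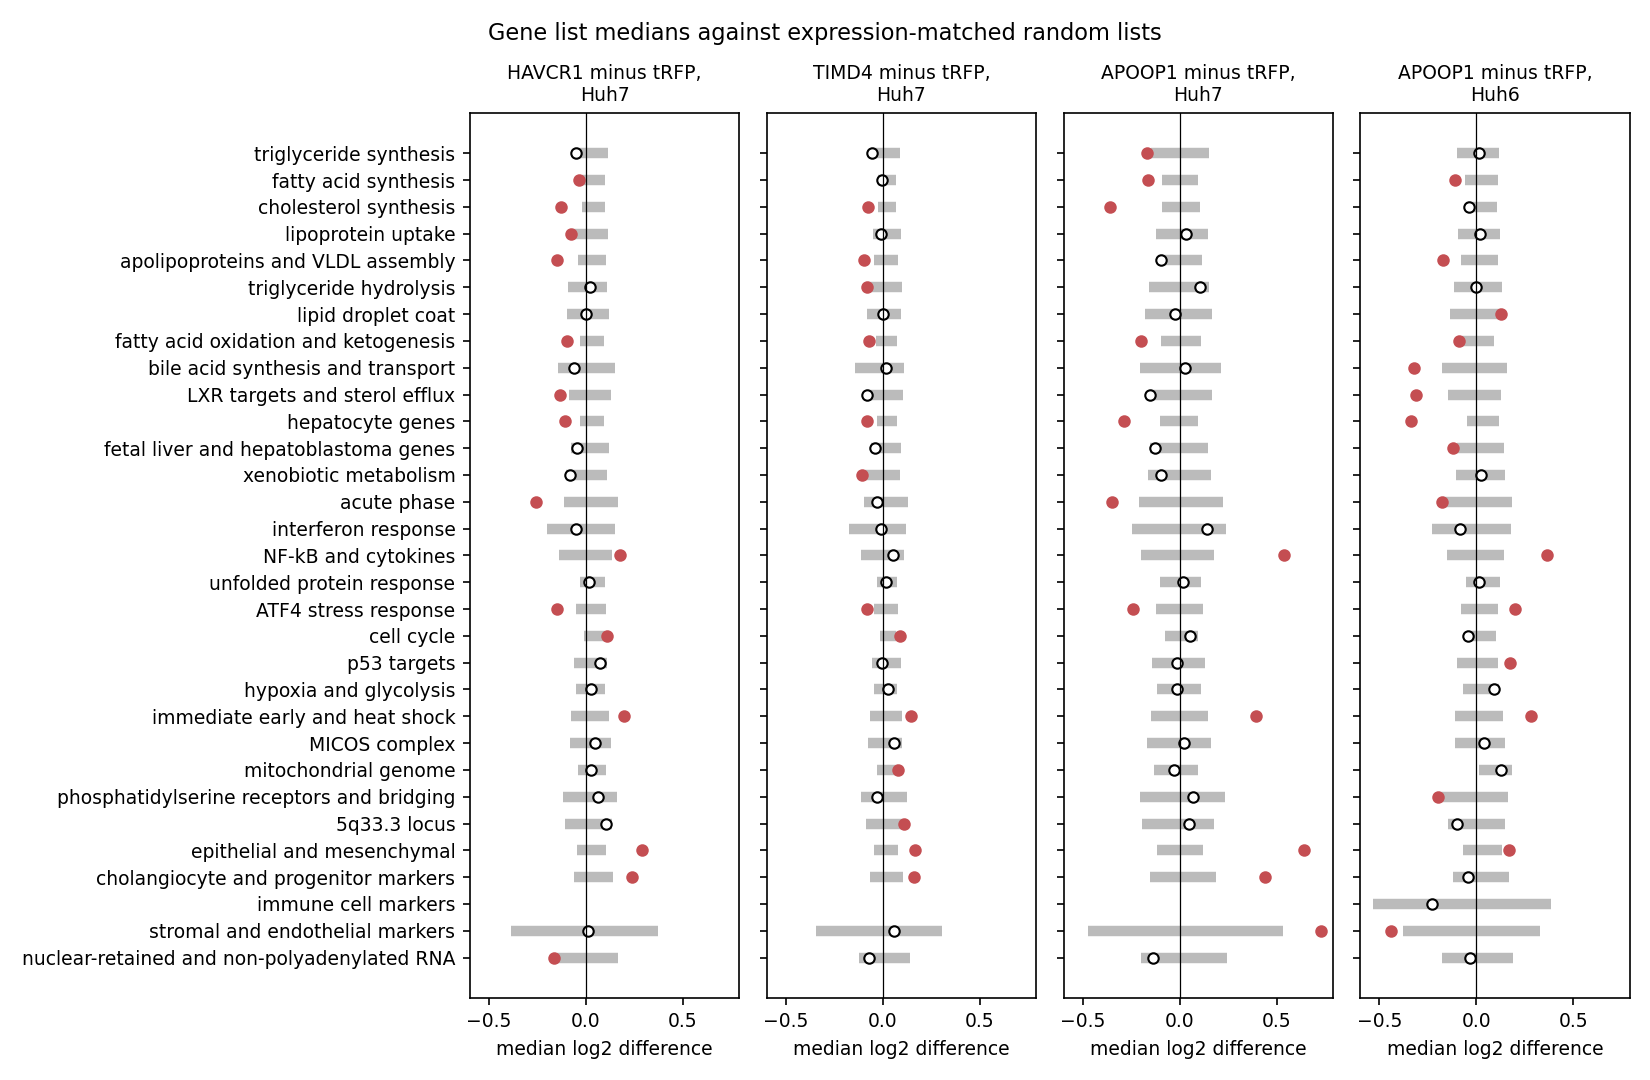
Median log2 difference of each fixed gene list in the 4 comparisons with a tRFP control. Grey bars span the central 95% of 10000 random lists of matched expression, red points lie outside that range and open points within it, and a missing point marks a list with too few measured members. Hepatocyte genes lie to the left of the range in all 4 panels, and epithelial and mesenchymal genes to the right, though the 3 Huh7 panels share a control. With members of at least 50 counts, the epithelial and mesenchymal list in Huh6 stood at 0.129 (percentile 97.21), within its range. Against the mean of the other Huh7 libraries, the epithelial and mesenchymal list was within its range for HAVCR1, and both lists turned direction for TIMD4. For HAVCR1 and TIMD4 that mean includes the APOOP1 library.

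KRT80 (ENSG00000167767, chromosome 12, 52168996 to 52192000) was the gene that passed the test of the APOOP1 libraries across both lines. APOOP1 itself was not detectably higher in the Huh6 APOOP1 library (10 against 4 counts). In Huh7, KRT80 was also higher with HAVCR1 (4.74-fold, 4.13 to 5.44) and TIMD4 (2.75-fold, 2.38 to 3.19), so its rise there was not particular to APOOP1. It was 6.48-fold (3.59 to 12.7) higher in Huh6, with 81 counts against 13, and 13.1-fold higher in Huh7, and edgeR's fit gave a log2 fold change of 3.54 ± 0.21 (SE, n = 2 lines, adjusted p = 0.0155), higher in 2 of 2 lines. Beside it, GPRC5A, a receptor induced by retinoic acid, was 3.28-fold (2.54 to 4.26) higher in Huh6 and 5.2-fold (4.23 to 6.44) in Huh7. The vasoconstrictor peptide EDN1 was 2.55-fold (1.53 to 4.40) and 4.75-fold (4.15 to 5.45) higher, and the cytoskeletal MAP1B 2.97-fold (2.21 to 4.03) and 5.33-fold (3.75 to 7.76). The cadherin CDH9 was at 0.361-fold (0.274 to 0.473) in Huh6 and 0.398-fold (0.225 to 0.677) in Huh7.

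KRT80 was the single gene of 16156 to pass edgeR's test at 5%, while 1177 genes had an unadjusted p under 0.05. GPRC5A (log2 fold change 2.06 ± 0.21) and EDN1 (2.03 ± 0.22) had an adjusted p of 0.14 in that edgeR fit, both higher in 2 of 2 lines. The fitted values of TGFB2, BICC1, TSPAN2, VIM and FGL1, also among the 10 smallest p-values, rested on Huh7, since these genes had at most 10 counts in either Huh6 library. The number of genes passing ran from 0 to 21 over the alternatives, and KRT80 missed the threshold in edgeR with a stricter filter (adjusted p = 0.059) and without the line block (adjusted p = 1.0), with a DESeq2 adjusted p of 9.38e-13 at the other end of the range.

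No member of any fixed list passed over all genes tested in that fit. Adjusted over the list alone, 9 of 31 hepatocyte genes fell, 7 of 17 NF-kB genes rose and 1 fell, 6 of 21 epithelial and mesenchymal genes rose, 4 of 21 ATF4 stress genes rose and 3 of 15 immediate early genes rose. Of 23 apolipoprotein genes 2 fell, of 27 fatty acid oxidation genes 2 fell, of 16 LXR targets 2 fell, of 15 lipid droplet coat genes 1 fell, and of 19 bile acid genes 1 rose and 3 fell. Of 18 p53 targets 3 rose, of 10 cholangiocyte markers 2 rose, of 23 hypoxia genes 1 rose, of 11 acute phase genes 1 fell and of 8 stromal markers 1 fell. Of 16 triglyceride synthesis genes, 25 fatty acid synthesis genes and 23 cholesterol synthesis genes, 0 passed in either direction.

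Of 10488 genes measured in both lines, 6 were at 2-fold or more higher in both, where 0.25 would be shared by independent lists, and 1 was lower in both, against 0.0355. In opposite directions, 1 gene was higher in Huh7 and lower in Huh6, and 0 the other way. Independence treats every gene as equally likely to reach 2-fold, so the expected numbers are rough. Across 10510 genes, not independent replicates, the APOOP1 differences of the lines were weakly correlated (Pearson's r 0.197, Spearman's rho 0.193), with the same sign in 56.4% of genes. The Huh6 APOOP1 difference correlated with the Huh7 HAVCR1 difference at 0.122 (rho 0.0917) and with the Huh7 TIMD4 difference at 0.113 (rho 0.0932). Whether these 3 coefficients differ was not tested.

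**Figure D3:**
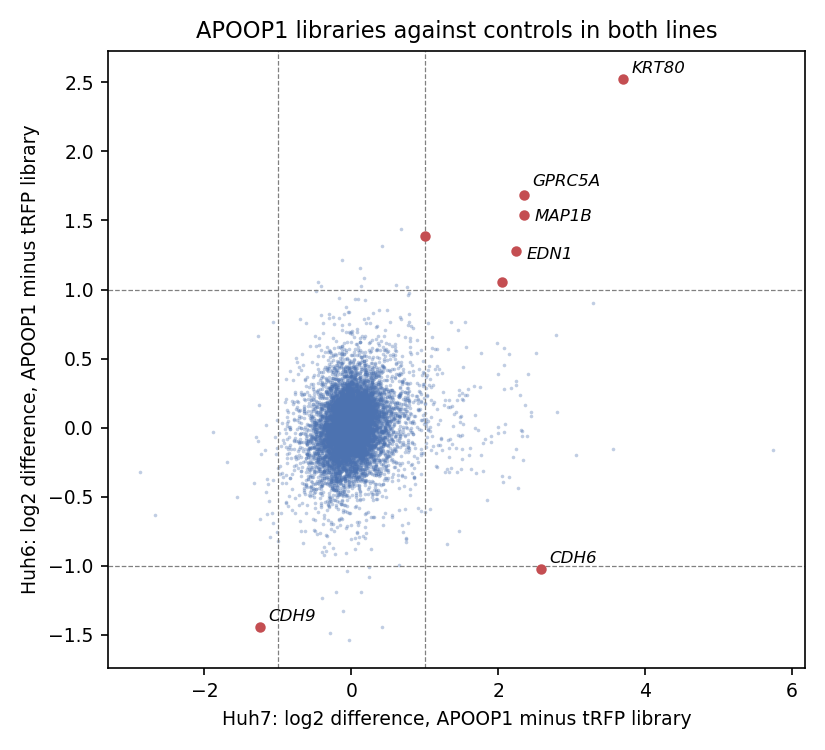
Log2 difference of the APOOP1 library from its tRFP control in Huh7 (horizontal) and in Huh6 (vertical), for genes measured in both lines. Each point is a gene, dashed lines mark 2-fold, and genes past 2-fold in both lines are red, with those given in the text labelled. KRT80 lies at 3.70 in Huh7 and 2.53 in Huh6, and CDH6 lies at 2.58 and -1.02.

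The HAVCR1 and TIMD4 libraries, compared directly to ask whether the receptors act differently, were the closest pair. Of 11501 genes measured, 4 were higher and 4 lower in the HAVCR1 library, TIMD4 itself among the lower. Simulated negative binomial counts of unchanged genes gave 9 genes at 2-fold here. Their spread was not measured between replicates of these libraries, so the 2-fold count cannot decide whether the receptors act differently. Besides TIMD4, and chosen after their values were seen, COL12A1 was 2.12-fold (1.49 to 3.06) higher and the channel gene ANO4 at 0.389-fold (0.233 to 0.631). Epithelial and mesenchymal genes stood at 0.12, cholangiocyte markers at 0.13 and NF-kB genes at 0.13. Phosphatidylserine receptors stood at 0.142 (percentile 99.16) and lay outside without the overexpressed genes too (percentile 98.14), while cholesterol synthesis stood at -0.052, lipoprotein uptake at -0.078, hepatocyte genes at -0.041, mitochondrial genome transcripts at -0.054 and nuclear-retained RNA at -0.17. With protein-coding genes only, nuclear-retained RNA turned to 0.0499 (percentile 65.24). NF-kB genes stood at 0.0906 (percentile 94.76) with members of at least 50 counts, and both then lay within the random range. In all, 10 of 30 lists lay outside, of which 6 no longer did so against unmatched random lists, cholesterol synthesis (percentile 4.33), lipoprotein uptake (2.98) and hepatocyte genes (5.45) among them.

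Genes that separated the APOOP1 library from the control also differed between the HAVCR1 and TIMD4 libraries. Of the 268 genes higher in the APOOP1 library than in the control, 240 (89.6%) were also higher in the HAVCR1 than in the TIMD4 library, a pair of libraries not used to select them. Of the 55 genes lower with APOOP1, 41 (74.5%) were lower in HAVCR1 than in TIMD4. In the Huh6 APOOP1 library, compared with its own control, the 164 of the 268 genes that were measured had a median log2 difference of 0.079, and the 31 measured of the 55 had a median of -0.371, against -1.15 for all 55 in Huh7. Across 11816 genes, differences without a shared library correlated at r = 0.341 (rho 0.268) for APOOP1 minus tRFP with HAVCR1 minus TIMD4. HAVCR1 minus tRFP correlated with APOOP1 minus TIMD4 at 0.512 (rho 0.373), and TIMD4 minus tRFP with APOOP1 minus HAVCR1 at 0.271 (rho 0.210).

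The lines differed far more than the constructs within a line. In Huh6, APOE, the ligand for remnant uptake, stood at 1160 ± 65.8 CPM (SD, n = 2) against 11.3 ± 1.28 (n = 4) in Huh7, and GPAM at 242 ± 43.9 against 5.22 ± 1.78. ALB stood at 50.4 ± 6.13 CPM in Huh6 against 2860 ± 379 in Huh7, FABP1 at 43.4 ± 8.66 against 476 ± 144, the desaturase FADS2 at 21.2 ± 2.55 against 642 ± 43.3 and MGLL, which hydrolyses monoglycerides, at 0.129 ± 0.183 against 218 ± 7.14. COL2A1, a cartilage collagen, stood at 2020 ± 177 in Huh6 and 0.0452 ± 0.0904 in Huh7, and SPP1, osteopontin, at 0.0959 ± 0.0476 and 2300 ± 227. Against a group floor of 3 counts, the laminin gene LAMA1 was at least 15800-fold higher in Huh6, and UCHL1, a ubiquitin hydrolase, at least 3600-fold lower.

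Of 16537 genes tested between the lines, 6300 were higher in Huh6 and 6272 lower at 5% in edgeR's quasi-likelihood test. The log2 fold change was 6.69 ± 0.098 (SE) for APOE (adjusted p = 2.21e-11) and -5.81 ± 0.17 for ALB (adjusted p = 1.02e-09). Of the apolipoprotein list 19 of 23 members were higher in Huh6 and 4 lower, of triglyceride synthesis 10 of 16 were higher and 4 lower, and of fatty acid synthesis 8 of 25 were higher and 15 lower, with the same numbers adjusted over the list alone. Cholesterol synthesis had 8 of 23 higher and 11 lower, triglyceride hydrolysis 4 of 16 higher and 9 lower, and p53 targets 14 of 18 higher and 1 lower. Libraries of a line differ in construct, so construct effects are part of this spread. Mitochondrial genes took 10.9% and 11.6% of the counts in the Huh6 libraries and 7.38% to 7.71% in the Huh7 libraries.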

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

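In this part, the tests on Huh6 RNA, the control library, YAP/TEAD targets, exchanged libraries and reads at APOO were chosen only after the results were seen, while those on GC content with length and on sequence identity were not. The APOOP1 effect lay 2-fold or more in opposite directions in the lines for 1 gene, and outside the random range in opposite directions for 2 lists. The difference was not tested, since each line holds 1 library per construct. The cadherin CDH6 had a log2 difference of 2.58 in Huh7 (203 against 34 counts) and -1.02 in Huh6 (60 against 129 counts). The ATF4 stress list had a median of -0.241 in Huh7, where members were split (9 above 0 and 12 below, mean -0.0717), and 0.201 in Huh6 (17 above and 3 below). The stromal and endothelial list had a median of 0.728 in Huh7, from 5 members, and -0.441 in Huh6, from 6 members, and against the mean of the 3 other Huh7 libraries the Huh7 median was 0.419 (percentile 96.71), no longer outside.

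The Huh7 APOOP1 library differed from its control by 2-fold or more in 323 genes. Huh6 RNA in that library is argued against, because 29 genes abundant in Huh6 and at 0 in the other Huh7 libraries together reached 0.00873% of their Huh6 level, and so is a trend with GC content and transcript length, since 92.6% of the 323 genes stayed at 2-fold after it was removed. An odd control library is argued against as the whole cause. Of the genes, 73.4% differed by 1.5-fold or more the same way from both the HAVCR1 and the TIMD4 libraries. An odd control may still add to the rest and to the list medians of all Huh7 constructs. A ribosomal RNA-like row held 12635 counts in the control and 1631 to 3138 in the other Huh7 libraries. Rows of that kind made up 0.0778% of the control's counts, and a link to the listed genes was not tested. A hypothesis formed on these data is that targets of YAP/TEAD and SRF, regulators of actin-linked genes, may account for part of the pattern: the list medians were 1.27 and 1.0 in Huh7, both at percentile 100, but the lists were chosen after such genes had been seen, so this decides nothing, and the medians were also above the random range with HAVCR1 (0.51 and 0.40) and TIMD4 (0.36 and 0.18), and in Huh6 for SRF (0.22) but not YAP/TEAD (0.052, percentile 79.9). Overexpression of APOOP1 and a difference between separately selected cell pools both stay open, since 1 library per group separates neither.

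HAVCR1, by fold, and APOOP1, by counts, stood little above their background in their own libraries. An exchange of the TIMD4 library with another Huh7 library is argued against, since TIMD4 was higher in its own with a lowest 95% bound of 38.4-fold, against a highest upper bound of 3.83 between libraries without its construct. Construct reads counted at APOO would raise APOO in both APOOP1 libraries, yet the higher of the upper bounds of its fold was 1.24. That argues against a large number of such reads, but not against one as small as the 10 counted at APOOP1. APOO had 594 counts in the Huh7 control and 181 in the Huh6 control, so few added reads would not show. Loss of APOOP1 reads that match APOO equally well is argued against, because the APOOP1 transcript shares 84.37% identity with APOO over 595 aligned bases. Whether the other 3 Huh7 libraries were exchanged among themselves stays open, since the lowest bound of the HAVCR1 fold was 1.41 while HAVCR1 differed about as much, by 0.723-fold (0.677 to 0.773), between the Huh6 libraries without its construct, and APOOP1 had at most 10 counts. Low expression of the constructs, or construct sequences that the annotated gene does not cover, may remain, and neither was tested. For HAVCR1 the control level was high, and its rise from 195 to 318 CPM was about as large as that of TIMD4, from 2.40 to 125.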

How the results depend on the processing

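The mean of the 3 others for APOOP1, the lists of protein-coding genes and the lists without the overexpressed genes were chosen after the data were seen; the other alternatives were planned. Scaling by DESeq2 factors, by library totals or by the deposited CPM, and a prior count of 0.5, left each 2-fold count within 1.5 times its main value. Counts of genes at 2-fold moved with the minimum count. At low counts counting error alone can reach 2-fold, as in the interval of APOOP1 in Huh6, 0.75 to 11.4 with 10 against 4 counts. How much of the move it makes up was not tested. At 10 and 200 counts the numbers were 501 and 23 for HAVCR1, 384 and 3 for TIMD4, 957 and 163 for APOOP1 in Huh7, 552 and 12 for APOOP1 in Huh6, and 381 and 2 for HAVCR1 against TIMD4. At 1.5-fold they were 342, 188, 1064, 451 and 136, since a lower threshold admits more genes. The share of higher genes for HAVCR1 moved from 73.3% to 42.3% at 10 counts. Against the mean of the 3 other Huh7 libraries the counts were 5 for HAVCR1, 14 for TIMD4 (3 higher and 11 lower) and 190 for APOOP1. For HAVCR1 and TIMD4 that mean holds the APOOP1 library, so its shift enters these counts. Beyond this the cause was not tested. The additive edgeR fit, which has no spread of its own for a lone library, gave 0 genes for HAVCR1 (211 at an unadjusted p under 0.05) and 1 for TIMD4 (135). Genes set apart at 10 counts, 200 counts and 1.5-fold were 91, 7 and 107 for tRFP, 232, 36 and 333 for APOOP1, and 55, 1 and 13 for TIMD4; for HAVCR1 they were 63 at 10 counts and 12 at 1.5-fold. The APOOP1 fit across lines gave 21 genes with DESeq2, whose own filter left 11276 genes without an adjusted p (GPRC5A, TGFB2, EDN1 and TSPAN2 among them), 8 without a filter on low counts, 0 with at least 50 counts in 2 libraries and 0 without the line block; the cause was not tested. Leaving out a library there leaves 0 residual degrees of freedom, so no such fit was run.

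Against the mean of the 3 other Huh7 libraries, 9 medians of lists called outside reversed; lists within their range were not counted. For HAVCR1, fatty acid synthesis became 0.0177 and acute phase 0.0317. For TIMD4, cholesterol synthesis became 0.0833, fatty acid oxidation 0.0377, hepatocyte genes 0.0365, ATF4 stress 0.0252, immediate early -0.063, epithelial and mesenchymal -0.143 and cholangiocyte markers -0.131. That mean contains the APOOP1 library, so the shift there enters each value. Restricting lists to protein-coding genes turned nuclear-retained RNA to 0.0611 for HAVCR1 and 0.0499 for HAVCR1 against TIMD4, since the non-coding members drop out. Of the other checks of lists called outside, 253 kept the call and its direction, though medians could shift, and 42 no longer lay outside; the lists outside numbered 46 in place of 66 with unmatched random lists and 64 without the overexpressed genes. KRT80 no longer passed under 2 of the settings of the fit across lines, while GPRC5A, TGFB2, BICC1, EDN1 and TSPAN2 passed without a filter on low counts. The genes named in single-library comparisons kept their direction and stayed within their counting intervals in 476 of 476 checks of scaling and prior count. The Huh6 and Huh7 difference ran from 10187 to 14158 genes, and from 11504 to 12716 with each library left out. APOOP1 had at most 10 counts in a library, so its difference in Huh6 was not detectable at this depth.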

Other observations

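In this part, the tests of a run of genes at 0 and of lists without the overexpressed genes were chosen only after the results were seen, while the fixed lists and the test of the lines were planned. Several fixed lists did not lie outside in any comparison with a control. The unfolded protein response stood at 0.018 for HAVCR1, 0.017 for TIMD4, 0.017 for APOOP1 in Huh7 and 0.011 for APOOP1 in Huh6. The MICOS complex, which holds APOO, stood at 0.048, 0.056, 0.021 and 0.041, hypoxia and glycolysis genes at 0.025, 0.026, -0.015 and 0.089, and interferon response genes at -0.053, -0.0088, 0.14 and -0.085, in the same order. All of these lay within the range of random lists, which was as wide as -0.248 to 0.24 for interferon response genes with APOOP1 in Huh7. Fetal liver genes stood at -0.048, -0.041, -0.13 and -0.12, of which the last lay outside. It no longer did so against unmatched random lists (percentile 6.21) or with protein-coding genes only (-0.0703, percentile 6.105). Phosphatidylserine receptors stood at 0.060, -0.031, 0.071 and -0.20, and genes of the 5q33.3 locus at 0.10, 0.11, 0.047 and -0.10. Both lists hold the overexpressed HAVCR1 and TIMD4, and without the overexpressed genes the values that had lain outside in comparisons with a control, -0.20 with APOOP1 in Huh6 and 0.11 with TIMD4, became -0.18 (percentile 6.61) and 0.076 (percentile 88.2), within the range. Immune cell markers had 2 measured members in Huh7 and were not tested there, and stood at -0.23 in Huh6, within the range.

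Between the lines, 5 of 22 ATF4 stress genes were higher in Huh6 and 10 lower, and 9 of 15 fetal liver genes were higher and 6 lower. NUPR1, a stress-induced chromatin regulator, stood at 190 ± 11.6 CPM (SD, n = 2) in Huh6 against 0.0155 ± 0.0309 (n = 4) in Huh7, while SLC7A11, the cystine transporter, stood at 20.2 ± 1.78 against 589 ± 55.5. NQO1, a target of the oxidative stress regulator NRF2, stood at 1.94 ± 0.279 against 2330 ± 263, and AKR1B10 at 14.0 ± 3.67 against 6090 ± 267. LIN28B, which blocks let-7 processing, stood at 1.78 ± 0.0497 against 235 ± 15.6, while the Wnt target NKD1 stood at 80.7 ± 0.279 against 0.534 ± 0.137. The glucose transporter SLC2A3 stood at 1470 ± 150 against 0.152 ± 0.143. All 7 passed edgeR's test at 5%. A ribosomal RNA-like row held 12635 counts in the Huh7 tRFP library and 1631 to 3138 in the other Huh7 libraries.

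APOOL, a MICOS gene related to APOO, had 0 counts in the 4 Huh7 libraries and 1130 in the 2 Huh6 libraries together. It lay in a run of 6 genes expressed in Huh6 and at 0 in Huh7 (BRWD3, SH3BGRL, APOOL, ZNF711, POF1B and CHM), between 80670854 and 86047562 on chromosome X. Of 383 X-linked genes expressed in Huh6, 34 (8.88%) were at 0 in Huh7, against 1.25% of autosomal ones. A chance run is argued against, as 2 of 10000 permutations of the genes at 0 gave one as long (permutation p = 0.0003). A lost segment or joint silencing may underlie it, and RNA counts do not tell these apart.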
